A study of Homo sapiens with 2 samples.

How the data were processed

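PAX5 binding was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in NALM6, an established human B-cell precursor leukaemia cell line. Per the labels, the cells received no treatment and were cultured for 4 days in a phenol red-free RPMI medium with 10% serum and 2 mM glutamine. The name of the ChIP alignment in the file header carries a time of 0 h, which no source used here explains. The series holds 2 samples, 1 ChIP sample made with an Abcam antibody to PAX5 and 1 input control made without antibody. The labels give NALM6 as the cell line of both samples. The title of the control also carries the name RXL, which no source used here explains, and every fold and control background below rests on this control. No replicate is given for either, so no p-value of a difference between samples was computed, and the intervals below cover counting error or the spread among peaks or chromosomes within this 1 comparison, not the spread between replicates.

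Reads were aligned with BWA to hg19, per the submitters' processing notes. Per the file headers, peaks were then called with MACS2 version 2.1.1.20160309 on a pooled ChIP alignment against a combined control alignment, with reads of 50 bp extended to 225 bp, no fragment model, an effective genome size of 2700 Mb and a q-value threshold of 0.05. How many libraries were pooled is not given in the sources used here. The header counts 46190180 ChIP tags and 25416858 control tags, of which 46190179 and 25416853 were kept at 1 tag per position. The header gives a redundant rate of 0 for both. A pool hides the spread between the libraries in it, and a peak that only 1 of them held cannot be recognised.

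The deposited table gives 4 measurements for each peak. The pileup signal is the number of extended ChIP reads over the summit, which MACS2 scaled by 0.550 to the depth of the control, per the file headers. The fold enrichment deposited by the authors is a ratio of pileup to local control background. The −log10 p and −log10 q values deposited by the authors come from the caller's Poisson comparison of these quantities. A second deposited file lists peak positions only, after a cleaning step that is not given in the sources used here. All values of a peak are the authors' own unless stated, and they were used only to describe and rank peaks within this list. Positions are on hg19 and count from 1.

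From these values, the number of ChIP reads over each summit was recovered by dividing the pileup by the scale. All pileups (100%) were whole reads within the rounding of 0.005 pileup units. The control background was recovered from the pileup and the fold with the caller's pseudocount of 1. The Poisson p recomputed from the recovered background was within 0.05 log10 units of the deposited one for 100% of the peaks. The caller takes as background the largest of the genome mean, a window of 225 bp at the summit, and windows of 1000 and 10000 bp. A background within 0.01 reads of the genome mean was assigned to it. Of the others, a whole number of reads (within 0.005 reads plus 0.0003 per read of background) was assigned to the summit window, and otherwise a multiple of 1 read in the 1000 bp window (within 0.005 reads) to that window. The split depends on this order, since 8.53% of all peaks had a background that was both and were counted under the summit window.

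Peak density was taken over the span from the first to the last summit of a chromosome, with exact Poisson 95% intervals of the count. Neighbouring peaks were compared with 100 seeded shuffles that kept each chromosome's number of peaks and placed them evenly over its span. Chromosome ends were defined as the first base, except on the acrocentric chromosomes 13, 14, 15, 21 and 22, and the end of the last listed peak. Intervals of medians and of ratios of medians or shares came from 1000 bootstrap draws of peaks, those of ratios of densities from the Poisson error of both counts on a log scale, and those of correlations from 2000 bootstrap draws of chromosomes. Single shares carry 95% Wilson intervals. Random sets of peaks matched on background or on chromosome were drawn 10000 times. Both lists were compared with bedtools 2.31.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The scripts were tested on simulated peaks: reads and background were recovered in 100% of 21361 simulated peaks, and evenly placed peaks gave a ratio to shuffles of 1.04 against a true value of 1.

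Before the data were examined, a promoter share within 1000 bp of transcription start sites, the share of peaks with a PAX5 motif within 100 bp of summits, 21 consensus motifs and 15 gene lists had been planned. These need the sequence and the gene annotation of hg19, which were not used here. The gene table at hand is on GRCh38.p14, and positions were not moved between builds. No peak is therefore assigned to a gene. Of the rule for named genes, the part that selects the 10 peaks of highest fold was kept, and those peaks are named by position. The other positions named were chosen after their values were seen. The other settings chosen then that could be run were a stricter q threshold, merging of close peaks, a restriction to chromosomes 1 to 22 and X, the cleaned list and stricter overlaps. The analyses of neighbouring peaks, chromosome ends, control background and chromosome densities, with their alternatives, were chosen after seeing the data. For chromosome ends, sets of the top 100, 500 and 2000 peaks were examined under 3 rankings, by fold, −log10 q and reads. The GRCh38.p14 table (RefSeq) was used only to count the protein-coding genes of each chromosome.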

Results

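PAX5 is a paired-domain transcription factor that establishes and maintains B-lymphocyte identity. Its binding was measured in untreated NALM6 cells by ChIP-seq against an input control labelled as NALM6. The ChIP pool held 46190180 tags and the input control 25416858, with 1 sample of each and no replicates. The question the design poses is where in the genome PAX5 occupancy exceeds the input.

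PAX5 enrichment over input was called at 21361 sites. They were distributed as 20921 peaks on the 22 autosomes, 392 on chromosome X, 23 on chromosome Y and 25 on 5 contigs outside the assembled chromosomes. Together they covered 9.58 Mb, or 0.355% of the effective genome size. The median peak was 383 bp wide, with 61 ChIP reads over its summit and a fold enrichment of 3.89 (95% bootstrap interval 3.86 to 3.91). Enrichment was moderate at most sites and high at few. Of all peaks, 5343 (25%) reached a fold of 5, 367 (1.72%) reached 10 and only 5 reached 20. The weakest summit still held 19 ChIP reads and the strongest 360. The −log10 q ranged from 1.30 to 172.

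The 10 sites of highest fold enrichment lay on 10 different chromosomes. The strongest was a 1324 bp peak on chromosome 17 from 212916 to 214239, with 180 reads at its summit (exact Poisson 95% interval 155 to 208) over a control background of 2.54 reads, a fold of 28.2. A peak on chromosome 8 from 1155933 to 1156956 followed with 262 reads (231 to 296), a background of 4.95 and a fold of 24.4. A peak on chromosome 6 from 68598689 to 68599560 had 202 reads (175 to 232), a background of 3.60 and a fold of 24.4. The peak on chromosome 5 from 402864 to 403512 reached a fold of 21.2, and that on chromosome 10 from 5881847 to 5883355 a fold of 20.2. The remaining 5 lay on chromosome 3 from 57102253 to 57102982, chromosome 4 from 300242 to 301004, chromosome 2 from 240513751 to 240515820, chromosome 1 from 2958960 to 2959479 and chromosome 21 from 18800191 to 18801344, with folds between 18.6 and 19.7. The cleaned list leaves out the summit of the chromosome 21 peak, for a reason that is not given in the sources used here. The counting intervals of neighbouring ranks overlapped. For the strongest peak the fold interval was 24.3 to 32.6 and for the second 21.6 to 27.5, with the control background taken as fixed, so the order of adjacent ranks was not resolved at this depth.

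Which sites counted as strongest depended on the measure. The chromosome 10 peak from 5881847 to 5883355 had rank 1 by −log10 q (172), rank 3 by reads (348) and rank 5 by fold. The chromosome 17 peak that led by fold had rank 23 by q and 361 by reads. Of the 10 highest by fold, 4 were among the 10 highest by q and 1 among the 10 highest by reads. Among the top 100, 58 were shared between fold and q and 36 between fold and reads. Across peaks, which are not independent replicates, fold and −log10 q, both computed from pileup and background, rose together (Spearman's rho 0.87). Fold and control background were inversely related (rho -0.36), which the division by the background favours by construction. Reads and control background rose together (rho 0.62), which calling favours, since a site with a higher background needs more reads to be called. The highest read count of the list, 360, was at a chromosome 8 peak from 130180030 to 130180999, where the control background was 24 reads and the fold 7.96. The widest enriched region spanned 6464 bp on chromosome 22 from 48975099 to 48981562 with a fold of 6.94. The next widest spanned 6055 bp on chromosome 17 from 56404826 to 56410880 with a fold of 14.1.

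PAX5 sites were unevenly distributed among chromosomes. Chromosome 22 carried 21.8 peaks per Mb (95% interval 20.2 to 23.4), chromosome 19 20.2 (19.1 to 21.4) and chromosome 17 17.0 (16.1 to 17.9), against a mean of 7.25 over chromosomes 1 to 22 and X. Chromosome 4 had 3.86 (3.59 to 4.15), chromosome 13 4.87 (4.44 to 5.33) and chromosome X 2.53 (2.28 to 2.79). The density on chromosome 19 was 5.24 times that on chromosome 4 (4.78 to 5.74), a difference far outside the counting error. The median fold varied less, from 3.77 on chromosome 17 to 4.03 on chromosome 20 among the autosomes. On chromosome X the median fold was 4.39, with 45 reads at the median summit.

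**Figure D1:**
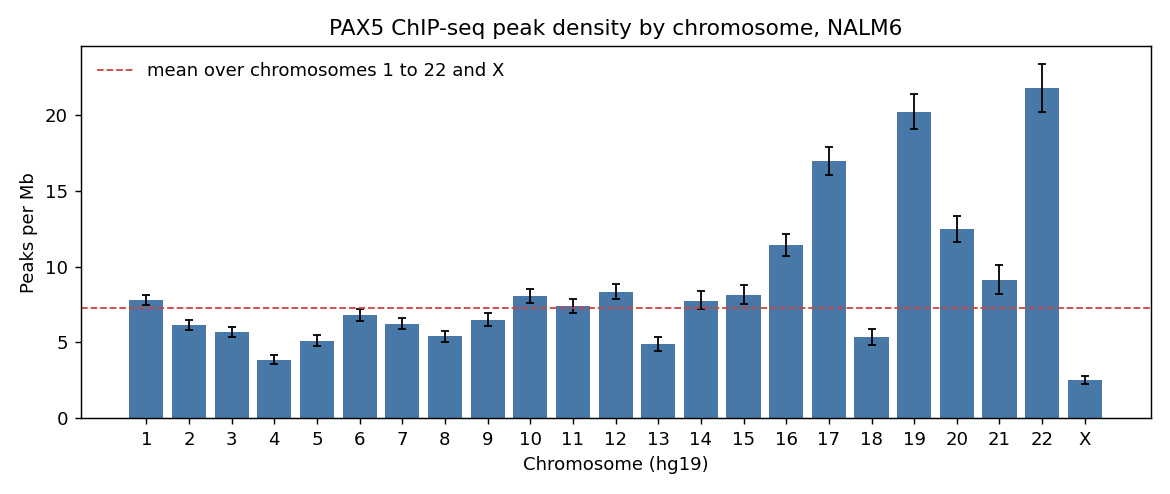
Peaks per Mb (vertical axis) for chromosomes 1 to 22 and X (horizontal axis), with exact Poisson 95% intervals as error bars and the mean of 7.25 as a dashed line. Chromosomes 22, 19 and 17 stand highest, at 21.8, 20.2 and 17.0 peaks per Mb, and chromosome X lowest, at 2.53.

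Chromosome X differed from the autosomes in both libraries. Its peak density was 0.337 times the autosomal one (0.305 to 0.372). The control background under its peaks had a median of 4.50 reads, 0.556 times the autosomal median of 8.10 (95% bootstrap interval of the ratio 0.514 to 0.619). When pileup and background of the autosomal peaks were both divided by 2, 83.0% of them still passed the lowest deposited −log10 p (3.74). The X density was then 0.405 times the autosomal one. The halving brings the autosomal background near that of X. The copy number of X was not examined, and fewer reads lower the chance that a site is called. The X density is therefore not a measure of binding alone. In the top 10% of peaks by −log10 q, the X density was 0.204 times the autosomal one. The −log10 q also depends on the number of reads, which was lower on X (median 45 against 61 over all peaks). By fold, no such further drop was seen. Chromosome X held 392 of all 21361 peaks, 13 of the 367 with a fold of at least 10 and 4 of the 100 of highest fold.

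Within chromosomes, peaks lay close together. Of the peaks on chromosomes 1 to 22 and X, 51.9% had another summit within 10 kb, compared with a mean of 16.1% and a highest value of 17.1% in 100 shuffles, a ratio of 3.23. The median gap between neighbouring peaks was 26.7 kb. Only 7.23% of the gaps were 500 bp or less, and after merging these the share with a neighbour was 45.1% against 14.9% in shuffles. Shuffling each peak within its own 1 Mb bin, which keeps the regional density, gave 28.7%, and the ratio fell to 1.81. The 296 densest of 2960 bins of 1 Mb held 40.8% of the peaks, against 23.9% in shuffles, and 662 bins held none. The shuffles over whole spans also placed peaks in any unsequenced stretches, where no peak can be called. This by itself raises the ratio of 3.23 and the contrast of the densest bins, to an extent that was not measured. The densest bin was on chromosome 19 from 2000001 to 3000000, with 85 peaks, 11.7 times the mean density, where no shuffle placed more than 41 peaks in any bin. It was followed by chromosome 17 from 79000001 to 80000000 with 70 peaks, chromosome 9 from 139000001 to 140000000 with 69 and chromosome 7 from 2000001 to 3000000 with 68.

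**Figure D2:**
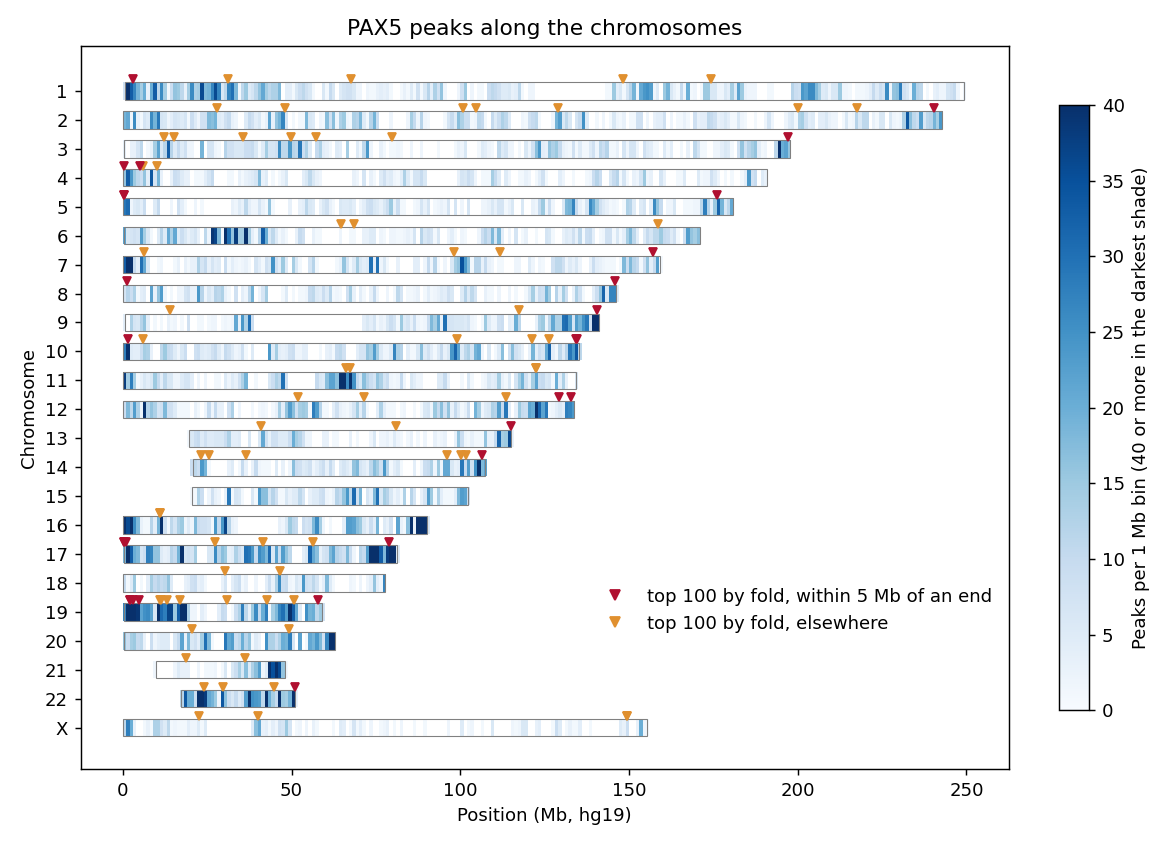
Position in Mb on hg19 (horizontal axis) of PAX5 peaks on chromosomes 1 to 22 and X (vertical axis), with the number of peaks per 1 Mb bin as shading and triangles for the 100 peaks of highest fold. Of these triangles, 29 lie within 5 Mb of a chromosome end (red) and the densest bin, on chromosome 19, holds 85 peaks.

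The sites of highest fold were found near chromosome ends more often than other sites. Of the 10 strongest, 6 lay within 5 Mb of an end. Among the top 100 the share was 29% and among the top 500 it was 28.8%, against 19.2% of all 21313 peaks on these chromosomes. The ratio to all peaks was 1.51 for the top 100 (95% bootstrap interval 1.09 to 1.98) and 1.5 for the top 500 (1.29 to 1.70). Without the 10 strongest peaks, in which the excess was first seen, the ratio of the next 100 was 1.41 (0.994 to 1.87), and within 10 Mb of an end that of the top 100 was 1.35 (0.990 to 1.70), both with intervals that reach 1. The share was 17.8% (Wilson interval 17.1 to 18.5) among peaks ranked below 10000. The excess depended on the ranking. Ranked by −log10 q, the top 100 had a ratio of 1.31 (0.893 to 1.77), and ranked by reads at the summit a ratio of 1.10 (0.725 to 1.51), neither distinguishable from 1 at this number of peaks. The top 500 by reads had a ratio of 1.26 (1.07 to 1.46). These comparisons of chromosome ends were made after the 10 strongest peaks had been seen. Their intervals treat peaks as independent, although peaks lay close together, and may be too narrow.

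**Figure D3:**
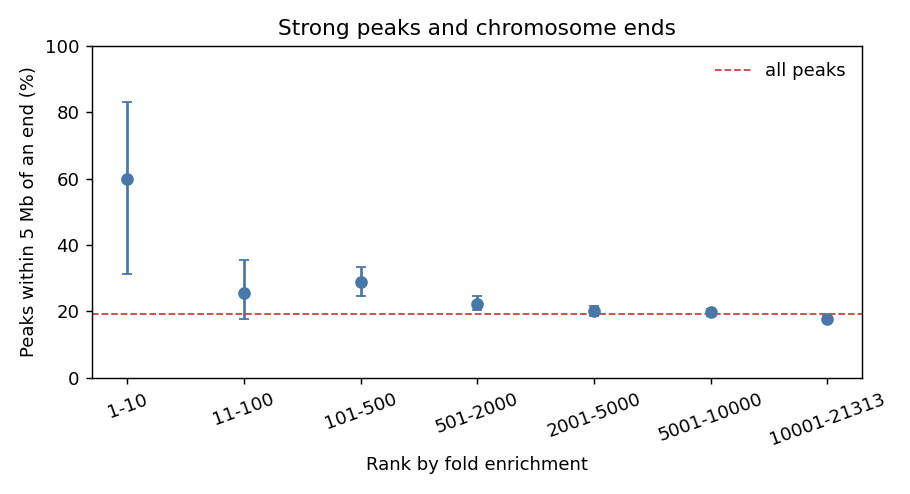
Share of peaks within 5 Mb of a chromosome end in percent (vertical axis) by rank of fold enrichment (horizontal axis), with Wilson 95% intervals as error bars and the share of all peaks, 19.2%, as a dashed line. The share is 60% in the 10 strongest peaks, where the interval is wide, 28.8% at the ranks after 100 up to 500 and 17.8% beyond rank 10000.

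The control was itself above its genome mean at the called sites. The control background at the summits had a median of 8.0 extended reads (95% bootstrap interval 8.0 to 8.1), 3.78 times the genome mean of 2.12. It was set by the window at the summit, as wide as an extended read, at 58.9% of the peaks, of which some may equally have been set by the 1 kb window (8.53% of all peaks), and by the 1 kb window alone at 37.4%, and only 0.889% of the peaks stood on the genome mean. The highest backgrounds were on an unplaced contig, GL000220.1, where 20 peaks had a median background of 60 reads and a median fold of 1.77. Among placed chromosomes the highest was 63.0 reads at a chromosome 17 peak from 41399750 to 41401253, with a fold of 1.73. A peak at such a site rests on many reads and a small ratio.

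**Figure D4:**
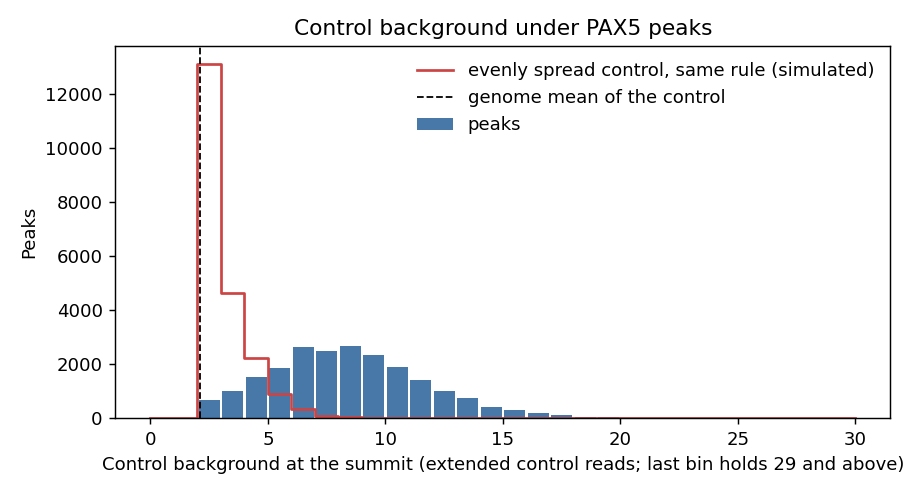
Number of peaks (vertical axis) by control background at the summit in extended control reads (horizontal axis), with the genome mean as a dashed line and an evenly spread simulated control under the caller's rule as a red line. The peaks centre on 8.0 reads, to the right of the genome mean of 2.12 and of the simulated control, whose median is 2.48.

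The cleaned list differed from the full call at 10 sites. Of the 21361 peaks, 21353 (99.96%) overlapped the cleaned list and 21351 were listed with identical borders. The 8 peaks left out had folds between 1.75 and 5.56. They included a pair on chromosome 21 between 9825658 and 9827263 and the chromosome 17 peak from 41465978 to 41466216, where the control background was 55.0 reads. A neighbouring peak on chromosome 17 from 41465316 to 41465647 was shortened by 85 bp. The chromosome 21 peak from 18800191 to 18801344, which has rank 10 by fold, was split into a pair of pieces, from 18800191 to 18800575 and from 18800998 to 18801344. The 422 bp removed between them held its summit at 18800890, with 237 ChIP reads over a background of 6.07. All 25 peaks on contigs outside the assembled chromosomes remained in the cleaned list.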

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

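The call of 21361 peaks became 19814 regions after merging peaks within 500 bp, 21313 on chromosomes 1 to 22 and X, 21354 in the cleaned list and 2139 among the top 10% by −log10 q, the last by construction. The share of peaks kept in the cleaned list was 99.96% at 1 bp and under a reciprocal overlap of 50%, and 99.95% for identical borders. The ratio of chromosome 19 to chromosome 4 density lay between 5.14 and 5.49 in the 3 alternatives run. The X to autosome density ratio of 0.337 became 0.405 with autosomal pileup and background halved. It was 0.204 in the top 10% by q, a measure that also depends on the number of reads, and stayed below 1. The ratio of close neighbours to shuffles, 3.23, was 3.03 after merging, 1.45 at 50 kb, 1.81 with shuffles within 1 Mb bins and 3.92 for peaks at or above the median fold, always above 1. The end ratio of 1.51 was 2.01 within 2 Mb and 2.82 with only the strongest peak of every run with gaps under 100 kb, a setting that favours ends by construction, since runs there held more peaks (8.30 per run against 3.56 elsewhere). It was 1.10 (0.725 to 1.51) when ranked by reads and 1.31 (0.893 to 1.77) by q, so that the excess in the top 100 was distinguishable from 1 only under the ranking by fold. Without the 10 strongest peaks it was 1.41 (0.994 to 1.87) and within 10 Mb 1.35 (0.990 to 1.70), both with intervals that reach 1. The background ratio of 3.78 was 4.25 in the top 10% by q and 1.62 at the peaks whose background was set by the 10 kb window or the genome mean, which are by construction those with the lowest local control. The causes of the other differences were not tested. Depth limits the order of the strongest peaks and, with 1 pooled ChIP, no spread between libraries can be given. The 34 further settings fixed for promoters, motifs and gene lists were not run, since they need the hg19 sequence and annotation, not used here. All alternatives except those of the peak number and of the cleaned list were chosen after seeing the data.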

Other observations

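The tests of the control background, of single loci, of background-matched sets of 100 peaks and of the ranking by reads were written before their results were seen. The tests of gene density, and of larger sets and joined loci near chromosome ends, were chosen after. All of them describe 1 pooled comparison of ChIP with input.

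Peak density rose with the density of protein-coding genes across chromosomes. Over the 22 autosomes and X (n = 23), peaks per Mb and RefSeq protein-coding genes per Mb (GRCh38.p14 counts over the hg19 span) gave Pearson's r = 0.868 (95% bootstrap interval 0.783 to 0.960) and Spearman's rho = 0.874, each with a permutation p of 1e-05, the smallest that 100000 permutations can give (adjusted p = 4e-05 over the 8 p-values of 4 relations, Benjamini-Hochberg). Without chromosomes 19 and 17, the farthest from the median gene density, r was 0.862. The density of peaks with a fold of at least 10 also rose with gene density (r = 0.755, rho = 0.614, permutation p = 0.00228 and 0.00252, adjusted p = 0.00504 for both). For the median fold, r was -0.0777 and rho -0.0899 (permutation p = 0.692 and 0.681, adjusted p = 0.692 for both), and for peak density against the median control background, r was 0.193 and rho -0.206 (permutation p = 0.257 and 0.346, adjusted p = 0.411 and 0.462). Chromosomes are not replicates of the experiment, so these p-values describe this peak list. Peak and gene densities were divided by the same span, which alone can raise their correlation, and the permutations do not account for this.

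The partial correlation of peak density and gene density given the median control background at the peaks was 0.873 (95% bootstrap interval 0.791 to 0.967). This decides nothing about control background that differs between chromosomes as a cause of this relation. The median was taken at called peaks only and differed little among the autosomes, so that holding it fixed could change little. Control background therefore stays open. For peak density against gene density, leaving out the acrocentric chromosomes gave r = 0.913 (0.678 to 0.974). This decides nothing about their unsequenced short arms, because each span began at the first summit. On chromosome 21 that summit, at 9825858, belonged to a peak left out of the cleaned list, and the span may take in part of the short arm. Unsequenced stretches within the spans stay open. GC bias of the libraries stays open, because the hg19 sequence was not used here. Binding in gene-rich chromatin may contribute, a hypothesis that was not tested, because peaks were not placed relative to genes.

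The excess of high-fold peaks near chromosome ends was noticed in the 10 strongest peaks, and the evidence for it is mixed. Ranking by reads gave the top 100 a ratio of 1.10 (0.725 to 1.51). This met the outcome set beforehand for a ranking that rewards low background (an interval with 1 in it). A limit added after the result is that the interval just reaches the ratio by fold (upper bound 1.515 against 1.514), so the rankings are not separated. Background matching of ranks 11 to 110 did not decide (27% near ends, percentile 94.6 of sets with a median of 20%). The median background of all peaks was 8.0 near ends and 8.1 elsewhere. Larger sets were examined only then. Those of the top 500 and 2000 under the 3 rankings, which overlap and are not separate results, had lower bounds above 1. The share of 28.2% at ranks 11 to 510 was above every background-matched set (median 20%, highest 26.8%) and every chromosome-matched one (highest 26.6%). These intervals and sets treat peaks as independent, although peaks lie in runs, so they may be too narrow. Loci were not joined for the larger sets. Several peaks of 1 locus stay open. The ratio of 2.82 (1.99 to 3.70) with 1 peak per run met the outcome set beforehand against this explanation (a lower bound above 1). It decides nothing, by a limit that was not part of the test as written: runs near ends held more peaks. Joining ranks 11 to 110 into 95 loci left 25.3% near an end (Wilson interval 17.6 to 34.8), an interval that includes the 19.2% of all peaks. For the top 100, chance, the ranking and repeated loci stay open, an excess in the larger sets is a hypothesis from the same data, and no biological explanation was tested.

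The control background under the peaks was 3.78 times the genome mean. The caller's choice of the largest window does not produce this from an evenly spread control, which had a median of 2.48 reads under the same choice against 8.0 observed. Whether an uneven control gives as much at sites without a peak was not tested, because no such sites were compared. ChIP reads mixed into the control would give an excess in proportion to the ChIP pileup. The excess per unit of pileup in the top 10% of autosomal peaks by pileup was 0.628 times that of all autosomal peaks (95% bootstrap interval 0.616 to 0.646). This was below the bound of 0.8 set beforehand. Choosing peaks by the pileup that divides the excess lowers this ratio by itself, to an extent that was not measured. The background also rose with pileup (median 10.8 reads in the top 10%, 8.10 in all autosomal peaks). Calling favours this rise without mixing, since a site with a higher background needs more reads to be called. Neither comparison decides. Mixing therefore stays open. Preferential recovery of open chromatin in input DNA is a candidate explanation that was not tested.

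The cleaned list leaves out the summit of the peak with rank 10 by fold, at a control background of 6.07 reads.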
